A study of Mus musculus with 4 samples.

How the data were processed

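RNA was measured in 4 libraries from IL-2 knockout BALB/c mice aged 15 to 16 days, made from lymph nodes and spleen. Per the labels, 2 libraries came from CD4 T cells sorted as CXCR5 positive and PD-1 high, called CD4 Tfh here, and 2 from CD8 T cells of the same CXCR5 and PD-1 phenotype, called CD8 Tfc. CXCR5 is the chemokine receptor that brings lymphocytes into B cell follicles, and PD-1 is an inhibitory receptor carried at a high level by follicular helper T cells. The series text describes the samples as pooled cells and as biological replicates. It does not say how many animals each pool held or whether equal replicate numbers came from the same pool. The labels name an Illumina TruSeq stranded total RNA kit and a TruSeq RNA library kit without saying which was used where.

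The deposited table holds read counts per gene that the authors made, with Trimmomatic, featureCounts, edgeR and limma and the mouse build GRCm38 named in the submitters' processing notes. The order, role and version of these tools, the aligner, the annotation and the strand setting of the counting are not given in the sources used here. Because 31.4% to 32.4% of the values of each library are not whole numbers, the deposited values were treated as estimated counts, and rounded to whole numbers before any test; raw counts had been assumed when the test was chosen. Per the file headers each library has its own column. The table has 23597 gene entries, of which 5243 are at 0 in all 4 libraries. Of the whole table, 1591 entries are additional copies of 1113 genes that also have an entry under the plain symbol. How reads matching several copies were counted is not given in the sources used here, so levels of such genes are uncertain. All 4 columns of the table were used, and the number of unused columns was 0.

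The total counts were 21504348 and 23448347 for CD4 Tfh 1 and 2 and 18075036 and 19256722 for CD8 Tfc 1 and 2. At these depths a floor of 3 counts corresponds to 0.142, 0.124, 0.167 and 0.157 CPM, the count scaled to a common library size, which covers counting error only. A chi-square comparison of the replicates gave 66.5 per degree of freedom in CD4 Tfh and 20.1 in CD8 Tfc, so neither pair was treated as 1 library deposited more than once. This compares the pairs with counting noise only.

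Counts were filtered with filterByExpr by group, which left 13466 gene entries, 896 of them additional copies. They were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with the group as the only term. P-values were adjusted with the Benjamini-Hochberg method over all entries tested, and an entry was called higher or lower at an adjusted p under 0.05. CPM values use the TMM-scaled library sizes. Log2 fold changes are CD8 Tfc over CD4 Tfh, and their standard errors (SE) were taken as the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.170. The steps were tested on simulated data with the means and library sizes of these samples. The changed genes were drawn from those with a mean CPM of at least 5, so the recovery does not cover genes below that level. The quasi-likelihood test recovered 84 of 100 genes changed 2-fold and 99 of 100 changed 4-fold among 13283 genes, with 19 false calls. As a share of all calls made, the false ones exceeded the 0.05 that the threshold aims at.

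Before the data were examined, 29 gene lists were fixed for T cell lineages, follicular help, cytotoxicity, regulation, signalling, metabolism, cell cycle and other cell types of lymphoid tissue. Lists with at least 5 tested members, 27 in all, were tested with camera of limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation, which takes its degrees of freedom from the libraries rather than from the genes, and fry were run beside it. For each list the members called over all genes were counted, and again with p-values adjusted over the list alone.

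The genes named were chosen by a rule, also fixed before. It took Il2, Cd4, Cd8a, Cd8b1, Cxcr5 and Pdcd1 in every sample. It added in each direction the 10 called genes with the largest log2 fold change, a mean CPM of at least 5 and no overlap between the groups, without T cell receptor and immunoglobulin segments and predicted genes. Of each list it took up to 4 called members with a mean CPM of at least 1. It always took Bcl6, Il21, Cd40lg, Icos, Foxp3, Prf1, Gzmb, Ifng, Tbx21, Eomes, Tox, Tcf7 and Mki67. This gave 77 genes. All other genes in the text, such as Myb, Krcc1, Klre1 and Cdh5, lie outside the rule and were named after their values had been seen. Coordinates of genes come from RefSeq on GRCm38.p6, in which 20573 of the table's symbols had a unique match.

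The RefSeq spans were also used to look for genes that overlap. Of the 77 named genes, 6 overlapped another gene's span, namely Cxcr5 (0.819% of its span), Nr4a2 (3.90%), Foxp3 (9.22%), Cd163l1 (11.5%), Ifi27l2a (61.8%) and Ebi3 (82.1%), and their levels are uncertain to that extent. Some genes lying inside another gene's span are listed at 0 in this table, among them B2m, Gzma, Cxcr6, Cxcl10 and Gpr183, and no level is reported for these. For 1 of the 77 named genes the result is not reported here.

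Alternatives tried were median-ratio size factors, library size alone, no filter or a filter of 10 counts, the DESeq2 1.42.0 Wald test, limma voom, the edgeR likelihood ratio test, a test against a 1.5-fold change, exclusion of globin and mitochondrial genes, the replicate number as a block, and each library left out in turn. Summing the copies of a gene into 1 entry was added after the data had been seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.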

Results

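The series set CD8 T cells with a follicular surface phenotype against CD4 follicular helper cells, both from IL-2-deficient mice, and the question addressed was which genes the populations express differently. IL-2 is a growth factor for T cells on which regulatory T cells depend, and mice that lack it develop autoimmune disease. Gene expression was available for 2 CD4 Tfh and 2 CD8 Tfc libraries, with total counts of 21504348 and 23448347 in CD4 Tfh 1 and 2 and 18075036 and 19256722 in CD8 Tfc 1 and 2.

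The deleted gene and the sorting markers were examined in every library before the comparison. Il2 (chromosome 3, 37120713 to 37125954) had 2.18 and 1.33 CPM in CD4 Tfh 1 and 2 and 0.889 and 0.261 CPM in CD8 Tfc 1 and 2. These values did not differ by edgeR's quasi-likelihood test (log2 fold change −1.61 ± 0.60 SE, adjusted p = 0.166). When the 3 entries of Il2 in the table were summed, they had 11.97, 7.59, 4.21 and 2.08 CPM in the same order, and the log2 fold change was −1.64 with an adjusted p of 0.0456. It was −2.71 without CD8 Tfc 1 (adjusted p = 0.00875) and −0.99 without CD8 Tfc 2 (adjusted p = 0.463), so Il2 passed the test under some treatments of the data and not under others. The part of Il2 removed in these mice is not given in the labels, so these reads do not check the genotype.

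Cd4, the coreceptor for MHC class II, had 1624 and 1748 CPM in the CD4 Tfh libraries and 50.7 and 5.23 CPM in CD8 Tfc 1 and 2. The CD8 coreceptor genes were at the opposite end. Cd8a (chromosome 6, 71373427 to 71379171) averaged 1403 ± 41.7 CPM in CD8 Tfc and 2.77 ± 2.45 CPM in CD4 Tfh (SD, n = 2 each). Cd8b1 (chromosome 6, 71322788 to 71337492) averaged 769 ± 34.5 and 5.98 ± 1.14 CPM. The gating genes were both lower in CD8 Tfc. Cxcr5 fell from 197 ± 20.8 CPM in CD4 Tfh to 74.1 ± 12.1 CPM (log2 −1.41 ± 0.18 SE, adjusted p = 0.00250). Pdcd1, which encodes PD-1, was 273 ± 28.5 CPM in CD4 Tfh and 123 ± 9.81 CPM in CD8 Tfc (log2 −1.15 ± 0.17 SE, adjusted p = 0.00452).

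**Figure D1:**
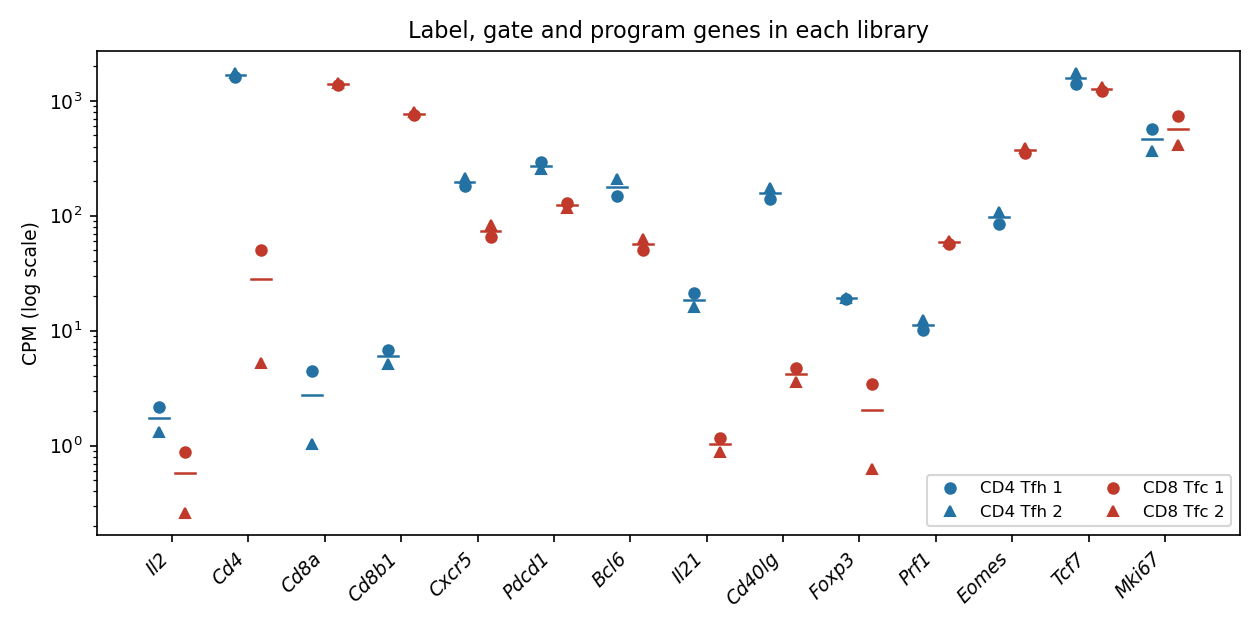
CPM on a log scale of 14 label, gate and program genes in the 4 libraries, with circles for replicate 1, triangles for replicate 2 and a bar for each group's mean. Cd4 lay at 50.7 CPM in CD8 Tfc 1 and at 5.23 CPM in CD8 Tfc 2, while Cd8a was at 1373 and 1432 CPM in these libraries.

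Among the genes higher in CD8 Tfc than in CD4 Tfh were the natural killer receptor genes Klrk1 and Klrd1, the perforin gene Prf1 and the chemokine gene Xcl1. Among the lower genes were the cytokine genes Il4 and Il21 and the CD40 ligand gene Cd40lg. In all, 539 gene entries were higher and 657 were lower in CD8 Tfc, 8.88% of the 13466 tested. Of these, 400 and 492 differed at least 2-fold, and 64 and 95 at least 8-fold. Counting each gene with several entries once, the calls came from 509 distinct genes that were higher and 637 that were lower. Without CD4 Tfh 2, 1106 entries were lower. Of the 657 lower entries, 33 lay in a block of chromosome 14 (3049285 to 7658936), whose ends were set by lower entries of predicted genes. Of the deposited values of these 33 entries 99.2% were not whole, against 44.4% for all tested entries, so their levels are uncertain.

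**Figure D2:**
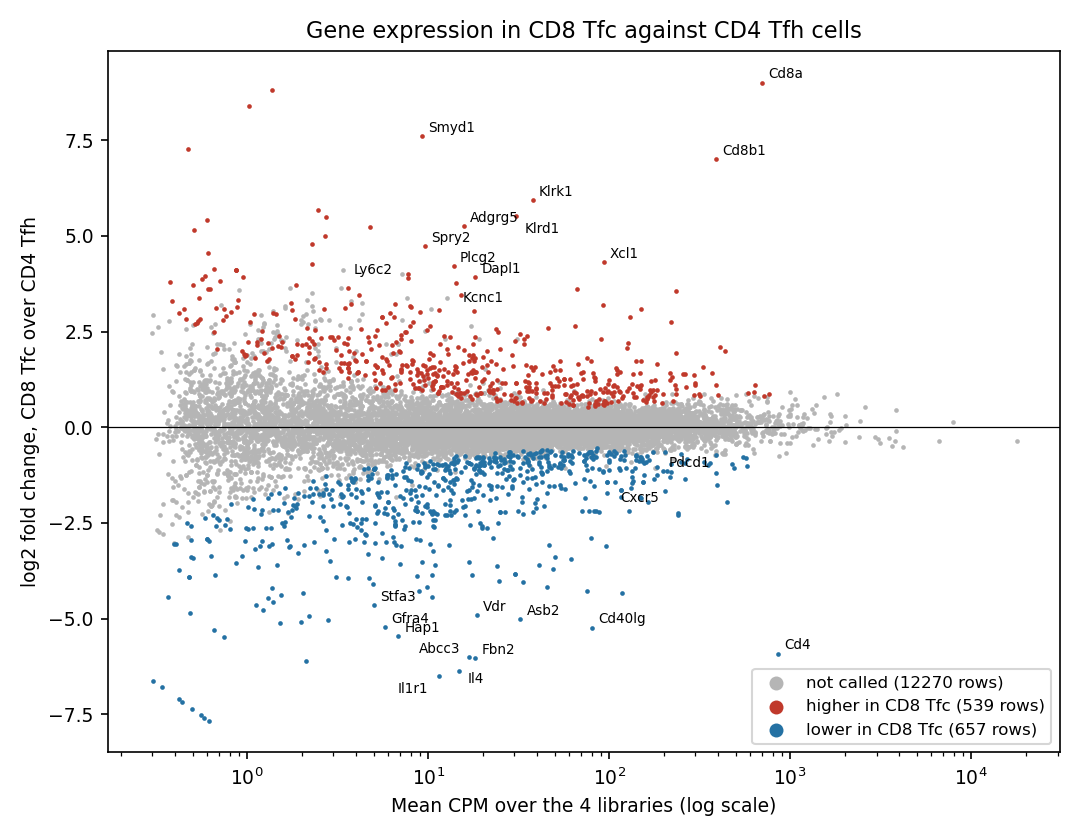
Log2 fold change of CD8 Tfc over CD4 Tfh against the mean CPM of the 4 libraries (log scale), with 1 point per tested gene entry and labels on the sorting genes and the 10 leading named genes in each direction. The 539 higher entries are red, the 657 lower ones blue, and Cd8a and Cd4 lie at 9.01 and −5.92. Cd8a was at 10.39 without CD4 Tfh 1 and 8.24 without CD4 Tfh 2, and Cd4 at −8.33 without CD8 Tfc 1 and −5.08 without CD8 Tfc 2. Limma voom gave −6.71 for Cd4.

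Apart from the sorting genes, the largest rise among the genes with at least 5 CPM that the naming rule ranked was that of Smyd1. This histone methyltransferase gene lies near the Cd8 genes on chromosome 6 (71213940 to 71262281). It averaged 18.5 ± 0.421 CPM in CD8 Tfc and 0.0949 ± 0.134 CPM in CD4 Tfh (log2 7.60 ± 0.55 SE, adjusted p = 2.7e-04, edgeR). With 3.84 and 0.24 deposited counts in CD4 Tfh 1 and 2, near and below the floor of 3 counts, the size of this fold is poorly known, and it was 11.56 without CD4 Tfh 1 and 6.52 without CD4 Tfh 2. Krcc1, between Smyd1 and Cd8b1, was not called (log2 −0.37 ± 0.16 SE, adjusted p = 0.238). The natural killer receptor genes Klrk1, which encodes NKG2D, and Klrd1, which encodes CD94, were raised by 5.94 ± 0.32 and 5.52 ± 0.30 on the log2 scale. The adhesion receptor gene Adgrg5 was raised by 5.26 ± 0.25, and Spry2, an inhibitor of receptor tyrosine kinase signalling, by 4.74 ± 0.27. Xcl1, a chemokine that attracts cross-presenting dendritic cells, averaged 178 ± 39.5 CPM in CD8 Tfc against 8.93 ± 1.79 CPM. Plcg2, a phospholipase of antigen receptor signalling, averaged 26.2 ± 5.59 CPM against 1.42 ± 0.136 CPM. The remaining leaders were Dapl1, Ly6c2 and Kcnc1, with log2 fold changes of 3.92, 3.89 and 3.78. Without CD4 Tfh 1, Klrk1 was at 6.63, Ly6c2 at 5.25 and Kcnc1 at 3.16. Without CD4 Tfh 2, Ly6c2 was at 3.13 and Kcnc1 at 4.92, and Ly6c2 was at 3.23 without CD8 Tfc 1.

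**Figure D3:**
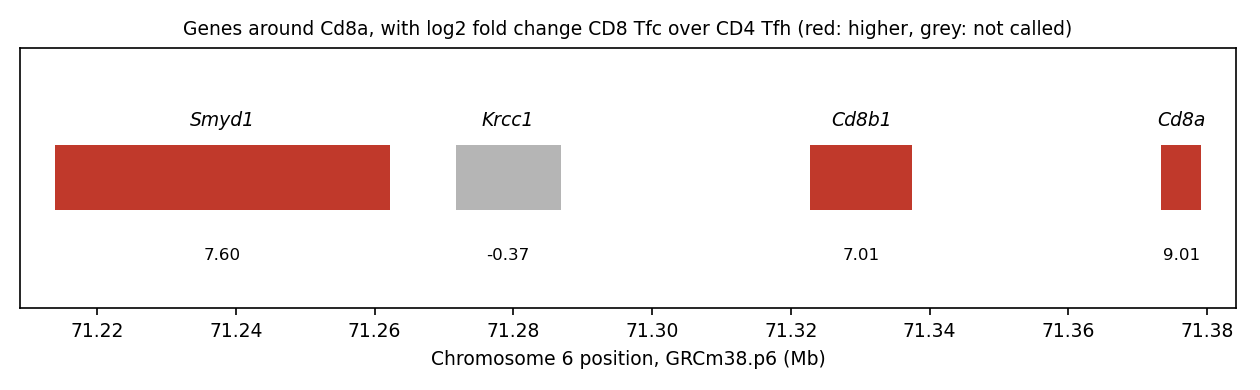
Map of the protein-coding genes from Smyd1 to Cd8a on chromosome 6 (GRCm38.p6, position in Mb), with the log2 fold change of CD8 Tfc over CD4 Tfh under each gene. Smyd1, Cd8b1 and Cd8a were higher, with 7.60, 7.01 and 9.01, and Krcc1 was not called.

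In the other direction, the interleukin 1 receptor gene Il1r1 averaged 22.7 ± 1.34 CPM in CD4 Tfh and 0.245 ± 0.125 CPM in CD8 Tfc (log2 −6.51 ± 0.33 SE, adjusted p = 8.5e-05, edgeR). Il4, the cytokine that drives IgG1 and IgE switching, was 29.3 ± 1.83 CPM against 0.353 ± 0.130 CPM (log2 −6.36 ± 0.29). Cd40lg, the ligand through which helper cells activate B cells, had 139 and 175 CPM in CD4 Tfh against 4.17 ± 0.866 CPM (log2 −5.24 ± 0.22). Fbn2 and Hap1, which encode fibrillin 2 and a huntingtin-associated protein, had log2 fold changes of −6.03 and −5.46. The transporter gene Abcc3 was 33.0 ± 7.38 CPM against 0.510 ± 0.0922 CPM. Gfra4, Asb2, the vitamin D receptor gene Vdr and Stfa3 followed at −5.22, −5.01, −4.91 and −4.64. Without CD8 Tfc 1, Il1r1, Fbn2, Hap1 and Stfa3 were at −7.12, −6.81, −6.36 and −7.37. Without CD8 Tfc 2, Gfra4 was at −6.05 and Stfa3 at −3.75, and Stfa3 was at −3.74 without CD4 Tfh 1 and −5.23 without CD4 Tfh 2.

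The follicular helper program was lower in CD8 Tfc as a group. Of its 29 tested members, 23 were lower, none was higher and 6 were not called. With p-values adjusted over the list alone, 25 were lower. Camera called the list down (adjusted p = 1.6e-23; adjusted p = 0.172 with an estimated correlation). Bcl6, the transcriptional repressor that specifies follicular helper cells, was 177 ± 42.5 CPM in CD4 Tfh and 56.6 ± 8.72 CPM in CD8 Tfc (log2 −1.65 ± 0.21, adjusted p = 0.00260). Il21, the main helper cytokine for germinal centre B cells, had a log2 fold change of −4.18 ± 0.29, and −3.90 when its 3 entries were summed. The costimulator Icos and the antagonist gene Sostdc1 were at −1.45 ± 0.16 and −3.70 ± 0.17. Cd40lg and Tnfsf8 are members of both this list and the CD4 lineage list. Cells without the CXCR5 and PD-1 phenotype were not measured, so these differences cannot be separated from those between CD4 and CD8 T cells.

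Ligands and cytokines of B cell help were lower in part. Among 18 tested members, 8 were lower, 2 were higher and 8 were not called, with 11 lower and 2 higher adjusted over the list alone. Camera called the list down (adjusted p = 4.5e-05; adjusted p = 0.270 with an estimated correlation). Cd40lg, Il4 and Il21, which the follicular helper list also holds, led the fall. The higher members were Tnfsf4, which encodes OX40 ligand (78.5 ± 14.1 against 13.1 ± 2.85 CPM, log2 2.58 ± 0.22), and Ifng, which encodes interferon gamma (149 ± 18.3 against 72.0 ± 6.26 CPM, log2 1.05 ± 0.16).

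The lineage lists separated the populations in the direction of their labels, which they are not independent of, since the cells were sorted on Cd4 and Cd8. The CD8 list had 11 of 14 members higher and none lower, and 13 higher adjusted over the list alone (camera adjusted p = 2.1e-15; adjusted p = 0.172 with an estimated correlation). Among them Eomes, a T-box factor of effector and memory CD8 cells, was 372 ± 24.9 CPM in CD8 Tfc and 96.8 ± 16.1 CPM in CD4 Tfh (log2 1.94 ± 0.18), and the related factor Tbx21 rose by 1.16 ± 0.17. The CD4 list had 8 of 12 members lower and 1, Myb, higher (camera adjusted p = 7.3e-10; adjusted p = 0.214 with an estimated correlation). Adjusted over the list alone, 9 were lower and 1 was higher. Zbtb7b, the CD4 lineage factor ThPOK, fell by 3.45 ± 0.20 on the log2 scale, and Tnfsf8, the CD30 ligand gene, fell by 2.30 ± 0.18.

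Cytotoxic genes rose in CD8 Tfc, although granzyme B did not stand out. Of 24 tested members, 14 were higher, 1 was lower and 9 were not called, with 16 higher and 1 lower adjusted over the list alone. Camera called the list up (adjusted p = 8.6e-12; adjusted p = 0.207 with an estimated correlation). Prf1, which encodes perforin, was 58.7 ± 2.23 CPM against 11.3 ± 1.74 CPM (log2 2.38 ± 0.18, adjusted p = 3.0e-04). Klrc1 rose by 5.50 ± 0.56, with 6.80 without CD4 Tfh 1 and 4.73 without CD4 Tfh 2. It had 3.58 and 0.75 deposited counts in CD4 Tfh 1 and 2, around the floor of 3 counts, so the size of its fold is poorly known. Klrc2 had 0.5 deposited counts in each CD4 Tfh library, which rounded to 0, and 2.04 ± 0.140 CPM in CD8 Tfc, which was at least 15.3-fold higher against the mean floor of 3 counts per CD4 Tfh library. Gzmb had 24.4 and 26.8 CPM in CD4 Tfh and 41.2 and 20.6 CPM in CD8 Tfc (log2 0.27 ± 0.29, adjusted p = 0.661), and its log2 fold change was −0.31 without CD8 Tfc 1.

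Naive, memory and stem-like genes were higher in part. In this list 8 of 20 members were higher and none lower, and 9 were higher adjusted over the list alone (camera adjusted p = 1.7e-04; adjusted p = 0.270 with an estimated correlation). Ly6c1 rose by 2.98 ± 0.52 and Bach2, a repressor of effector differentiation, by 1.36 ± 0.21. Ly6c1 was at 3.94 without CD4 Tfh 1 and 2.35 without CD4 Tfh 2. Tcf7, which encodes TCF-1, was 1570.2 ± 258 CPM in CD4 Tfh and 1267 ± 86.1 CPM in CD8 Tfc and was not called (log2 −0.31 ± 0.21, adjusted p = 0.464).

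Regulatory T cell genes were lower in CD8 Tfc. Of 20 tested members, 12 were lower, none was higher and 8 were not called, with 16 lower adjusted over the list alone. Camera called the list down (adjusted p = 2.1e-13; adjusted p = 0.207 with an estimated correlation). Foxp3, the defining factor of regulatory T cells, had 19.0 and 19.3 CPM in CD4 Tfh and 3.45 and 0.627 CPM in CD8 Tfc 1 and 2 (log2 −3.24 ± 0.56, adjusted p = 0.01004). Gpr83, the integrin gene Itgb8 and Ebi3, a subunit of IL-27 and IL-35, fell by 3.95 ± 0.53, 3.87 ± 0.23 and 2.94 ± 0.47. Without CD8 Tfc 1, Foxp3, Gpr83 and Ebi3 were at −4.92, −5.39 and −4.16, and without CD8 Tfc 2 at −2.49, −3.25 and −2.30. Another gene's span covers 82.1% of Ebi3, so its level is uncertain. In CD8 Tfc 1, where Cd4 was at 50.7 CPM, 5 of the 12 lower members were over 2 times their level in CD8 Tfc 2.

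The list of inhibitory receptors and exhaustion genes had called members in both directions. Of 19 tested members 3 were higher, namely the nuclear receptor gene Nr4a2 (log2 1.73 ± 0.18), Cd160 (1.45 ± 0.14) and Lag3 (1.39 ± 0.19), and 2 were lower, namely Btla (−1.34 ± 0.16) and Pdcd1. Adjusted over the list alone, 4 were higher and 6 lower, and camera did not call the list (adjusted p = 0.967). Tox, a factor of chronically stimulated CD8 cells, was 199 ± 6.84 CPM in CD4 Tfh and 206 ± 10.3 CPM in CD8 Tfc (log2 0.05 ± 0.15, adjusted p = 0.891), and its log2 fold change was −0.00167 without CD8 Tfc 1. Chemokines and trafficking receptors had 8 members higher and 6 lower of 26 tested, and 12 and 6 adjusted over the list alone (camera adjusted p = 0.241, and 0.0461 without CD8 Tfc 1, with the direction up). Besides Xcl1, they included Ccr8 and Ccr4, which fell by 2.50 ± 0.42 and 2.15 ± 0.20.

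T helper cytokines and factors had 3 members higher, among them Ifng and Tbx21, and 3 lower, namely Il1r1, Il4 and Ccr6 (−1.21 ± 0.25), of 12 tested, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.399). In the IL-2 and STAT5 pathway, 2 of 23 members were higher, Il7r (log2 1.14 ± 0.14) and Il4ra (0.71 ± 0.14), and 1 was lower, Lta (−1.06 ± 0.25), with 2 and 2 adjusted over the list alone (camera adjusted p = 0.807). The call of Il4ra was lost without CD8 Tfc 1 or 2, and that of the plain entry of Lta without any 1 of the 4 libraries. With the entries of Lta summed, its log2 fold change with all libraries was −1.09 (adjusted p = 0.00799, edgeR's quasi-likelihood test). T cell receptor signalling and early activation had 3 members higher and 4 lower of 26, and 6 and 7 adjusted over the list alone (camera adjusted p = 0.967). Spry2 and Nr4a2 were among the higher ones, and Spry1 (−1.20 ± 0.22) and Egr3 (−1.17 ± 0.18) among the lower. The interferon response had Ifit3 higher (1.24 ± 0.18) and 5 members lower of 33, including Ifi27l2a (587 ± 270.1 against 207 ± 4.48 CPM), Isg20 (−0.99 ± 0.16) and Iigp1 (−0.98 ± 0.17), with 2 and 7 adjusted over the list alone (camera adjusted p = 0.807).

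Metabolic and growth genes showed few differences between the groups. Glycolysis had 1 member higher and 4 lower of 25, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.413). The lower ones were Aldoc (−2.09 ± 0.32), Bnip3 (−1.49 ± 0.35), Hif1a (−0.81 ± 0.18) and Pdk1 (−0.78 ± 0.17). Calls of Hif1a and Pdk1 were lost without CD8 Tfc 1 or 2, and that of Bnip3 without CD4 Tfh 1. No member was called by edgeR's quasi-likelihood test, over all genes or adjusted over the list alone, among 48 cell cycle genes, 13 histone genes, 51 oxidative phosphorylation genes, 13 mitochondrially encoded genes and 65 ribosomal protein genes. At an unadjusted p under 0.05 there were 0, 0, 1, 0 and 1 of them, and DESeq2 called 0, 0, 0, 0 and 1, while limma voom called none. Camera gave adjusted p-values of 0.257, 0.765, 0.333, 0.151 and 0.637 for these lists. With the replicate number as a block it called the mitochondrially encoded list down (adjusted p = 0.0329). Mki67, the proliferation marker, had 572 and 365 CPM in CD4 Tfh 1 and 2 and 730 and 411 CPM in CD8 Tfc 1 and 2 (log2 0.28 ± 0.31, adjusted p = 0.669), with log2 fold changes of −0.04 without CD4 Tfh 2 and −0.19 without CD8 Tfc 1. The summed cell cycle genes were at 4663, 2853, 5096 and 3041 CPM in the same order, and camera's direction for them turned with the library left out. It was up without CD4 Tfh 1 (adjusted p = 8.2e-08) or CD8 Tfc 2 (9.8e-08) and down without CD4 Tfh 2 (0.0280) or CD8 Tfc 1 (0.00942). Mitochondrial genes took 7.30% of the counts of CD4 Tfh 1 and 3.80%, 4.71% and 3.80% of those of CD4 Tfh 2 and CD8 Tfc 1 and 2. Without CD4 Tfh 1 the ribosomal protein (3.0e-13) and oxidative phosphorylation (0.0112) lists were called up. Without CD4 Tfh 2 both were called down (1.0e-06 and 5.3e-07), and so was the mitochondrially encoded list (7.1e-07, and 0.0326 without CD8 Tfc 1). The histone list was called up without CD8 Tfc 2 (0.00141).

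**Figure D4:**
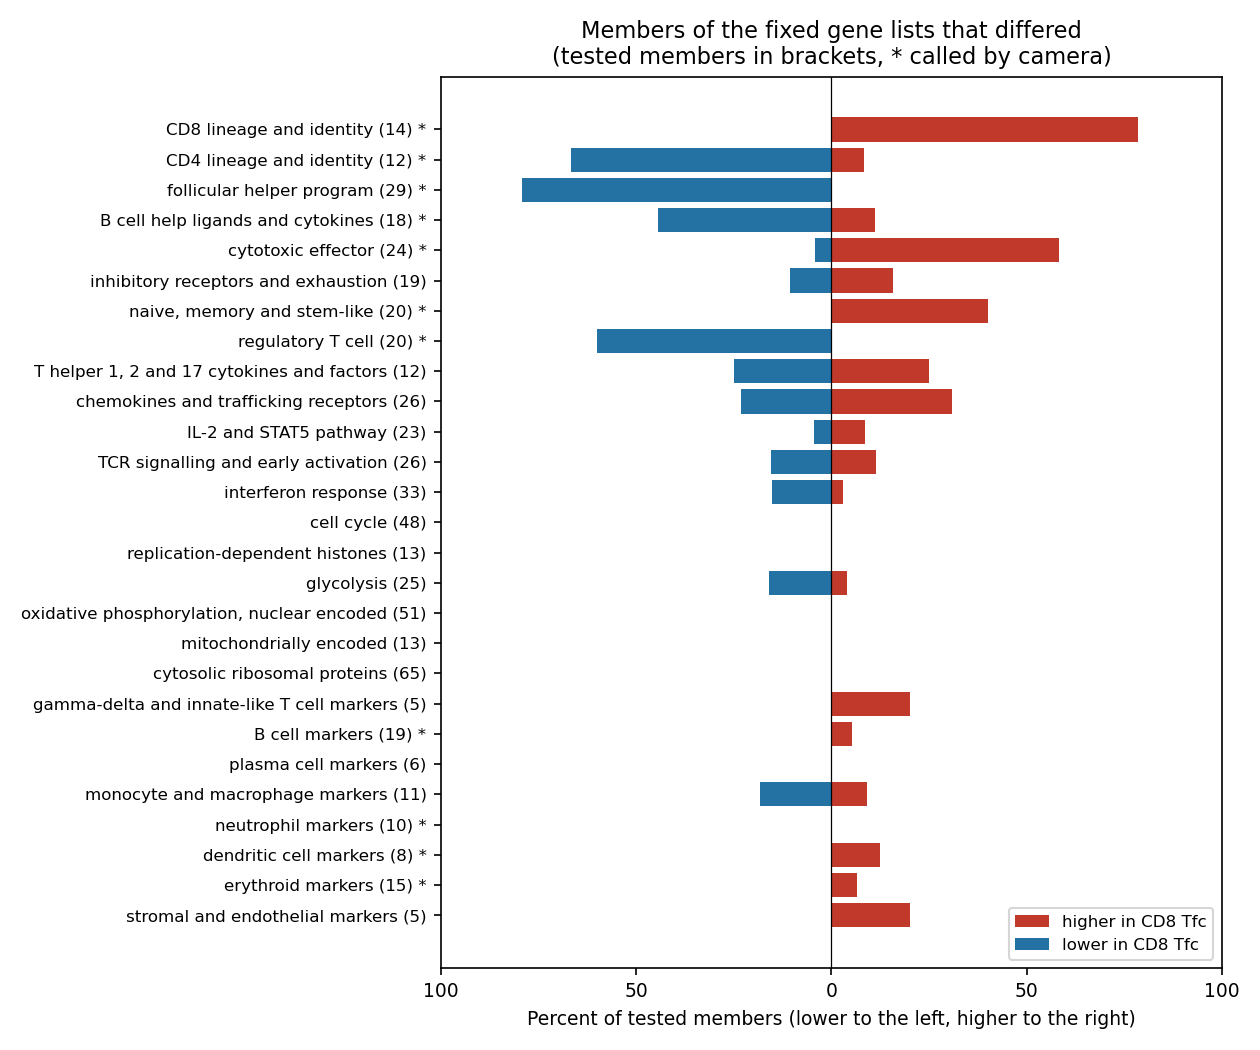
Percent of tested members of each of the 27 tested gene lists that were higher (red, right) or lower (blue, left) in CD8 Tfc, with the number of tested members in brackets and a star where camera called the list at the preset correlation. The follicular helper list had 23 of 29 members lower and the CD8 list 11 of 14 higher.

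Markers of other cell types were present, and several were high in CD8 Tfc 1. B cell markers summed to 379 CPM in CD8 Tfc 1 and 160 CPM in CD8 Tfc 2, against 175 and 175 CPM in CD4 Tfh. Neutrophil markers summed to 188 and 15.1 CPM in CD8 Tfc 1 and 2 and to 30.5 and 2.78 CPM in CD4 Tfh 1 and 2. Erythroid markers summed to 485 and 218 CPM in CD8 Tfc and to 303 and 179 CPM in CD4 Tfh. In CD8 Tfc 2 most of the erythroid sum came from Tfrc alone, and most of the B cell sum from Cd22. Camera called the B cell (adjusted p = 0.0227), neutrophil (0.00495), dendritic cell (0.0289) and erythroid (0.0382) lists up. With an estimated correlation the adjusted p was 0.979, 0.902, 0.685 and 0.979. Without CD4 Tfh 2 the B cell, neutrophil and erythroid calls were lost (adjusted p = 0.225, 0.225 and 0.376), and that of the erythroid list was lost with globin and mitochondrial genes excluded (0.0915). Without CD8 Tfc 1 the B cell, dendritic cell and erythroid calls were lost (adjusted p = 0.502, 0.0638 and 0.707), the neutrophil list was still called up (0.0206), and the medians of the B cell, neutrophil and erythroid lists were −0.03, 0.04 and −0.58 on the log2 scale. The follicular helper, B cell help, lineage, cytotoxic, naive and memory, and regulatory lists were still called without this library, and 511 entries were higher and 648 lower.

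Single members of these lists passed the test, of 19 B cell, 8 dendritic cell and 15 erythroid markers tested. Cd79b, a chain of the B cell receptor complex, had 21.8 and 7.11 CPM in CD8 Tfc 1 and 2 and 2.47 and 0.829 CPM in CD4 Tfh (log2 3.14 ± 0.63, adjusted p = 0.0190). Itgax, which encodes CD11c, averaged 5.20 ± 1.29 CPM in CD8 Tfc and 0.160 ± 0.109 CPM in CD4 Tfh (a 32.1-fold difference, adjusted p = 0.00122, edgeR). With 5 and 2 deposited counts in CD4 Tfh 1 and 2, around the floor of 3 counts, the size of this fold is poorly known. The carbonic anhydrase gene Car2 rose by 1.98 ± 0.44. Without CD8 Tfc 1, Cd79b was at 2.12 and Car2 at 1.25. Without CD4 Tfh 1, Cd79b was at 4.11 and Itgax at 5.86, and without CD4 Tfh 2 at 2.51 and 4.38. None of 10 neutrophil markers was called by edgeR's quasi-likelihood test or limma voom, with 7 at an unadjusted p under 0.05, 2 called by DESeq2 and 3 by the edgeR likelihood ratio test. Adjusted over the list alone, 1 B cell, 2 neutrophil, 3 dendritic cell and 1 erythroid marker were higher and none was lower. Among 11 monocyte and macrophage markers, Cd68 (1.19 ± 0.18) was higher and Vcam1 (−1.88 ± 0.34) and Hmox1 (−0.79 ± 0.19) were lower, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.812), and without CD8 Tfc 1 the call of Hmox1 was lost and Vcam1 was at −2.52. Cd163l1 (2.74 ± 0.42) was the only called one of 5 gamma-delta T cell markers, over all genes and adjusted over the list alone (camera adjusted p = 0.178), and was at 3.61 without CD4 Tfh 2. None of 6 plasma cell markers was called by edgeR in either way, by limma voom or by DESeq2, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.967). Only 7 of the 12 plasma cell, 21 of the 24 B cell and 6 of the 10 gamma-delta markers fixed had an entry, so these lists are partial. Without CD8 Tfc 2 the gamma-delta, plasma cell and monocyte lists were called up (adjusted p = 0.00977, 0.00410 and 7.9e-07). Cdh5 was higher among 5 stromal and endothelial markers, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.807). Natural killer and platelet lists had 4 and 2 tested members and were not tested as lists. Natural killer markers summed to 17.3 and 3.45 CPM in CD8 Tfc 1 and 2 and to 2.89 and 2.78 CPM in CD4 Tfh 1 and 2. Klre1 was higher in the former, and no platelet marker was called by edgeR, limma voom or DESeq2 or had an unadjusted p under 0.05, with the same counts adjusted over the list alone. The calls of Klre1 and Cdh5 were lost without CD8 Tfc 1.

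**Figure D5:**
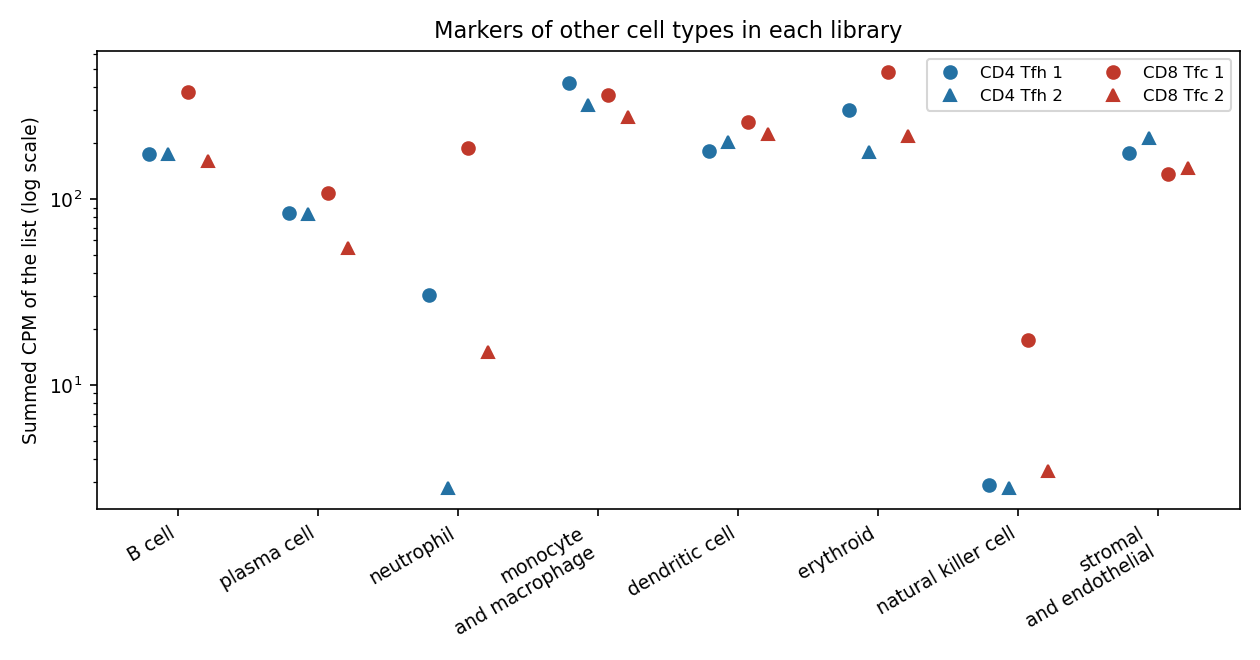
Summed CPM (log scale) of 8 lists of markers of other cell types in each of the 4 libraries, blue for CD4 Tfh and red for CD8 Tfc, with circles for replicate 1 and triangles for replicate 2. Neutrophil markers ranged from 2.78 CPM in CD4 Tfh 2 to 188 CPM in CD8 Tfc 1.

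The signs of median, mean and camera differed for the IL-2 and STAT5, T cell receptor signalling, ribosomal protein and monocyte lists, none of them called. Fry, which asks only whether the genes of a list move one way on balance, gave adjusted p-values from 0.00569 to 0.0492 for the 7 T cell lists that camera called and for the chemokine list. With 2 pooled libraries per group, the p-values of single genes measure the spread between these pools, with variation estimates shared across genes. Those of camera at the preset correlation compare the members of a list with the other genes. Genes rather than pools are their units, so they do not measure the spread between pools. No list was called by camera with an estimated correlation. That setting takes its degrees of freedom from the 4 libraries rather than from the genes, which leaves little power. Its adjusted p was higher even where the estimated correlation lay below the preset 0.01, at −0.00588 for the follicular helper list and −0.0476 for the CD8 list. For those lists the higher values do not come from correlation between genes.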

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

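The test of copies summed into 1 entry was chosen after the data had been seen, and all other alternatives before. No called gene entry changed sign under any alternative. Of the named genes, Mki67, Gzmb and Tox, not called in any of them, changed sign when a library was left out. Il2 was called lower with the replicate block (adjusted p = 0.0163), with copies summed (0.0456) and without CD8 Tfc 1 (0.00875). The counts of 539 higher and 657 lower entries stayed within 1.5 times under median-ratio factors, library size alone, both filters, DESeq2 (639 and 706), limma voom (544 and 659), exclusion of globin and mitochondrial genes, and summed copies (478 and 622). The edgeR likelihood ratio test called 818 higher and 906 lower, and the cause was not tested. The test against a 1.5-fold change, which by construction asks for a larger effect, called 256 and 343. With libraries left out in turn, 430 to 755 entries were higher and 522 to 1106 lower, from fewer samples, the lone sample being assumed to vary like the other group. The higher share was 59.1% without CD8 Tfc 2 and 45.1% with all libraries.

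Camera called 11 lists, 7 up and 4 down, 0 with an estimated correlation, 11 to 16 with 1 library left out, and 10 with globin and mitochondrial genes excluded, where the erythroid call was lost. The labels do not say that equal replicate numbers share a pool. The deviations of CD4 Tfh 1 and CD8 Tfc 1 from their group means correlated at 0.412 across genes, and the second principal component, 21.5% of the variance, separated the numbers. With the replicate number as a block, 1450 entries were higher and 1532 lower, including all 1196 called without it, and camera called 12 lists. Among these the B cell (adjusted p = 7.7e-08), neutrophil (1.3e-11) and erythroid (1.2e-06) lists were up, and the mitochondrially encoded list (0.0329), not called without the block, was down. All adjusted p-values of lists in this paragraph are from camera at the preset correlation.

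Of the named genes, DESeq2 lost the calls of Lta and Bnip3, the test against a 1.5-fold change lost 13, and the single left-out libraries lost 1 to 5 each, from Lta, Bnip3, Il4ra, Hif1a, Pdk1 and Hmox1. Depth limits genes near the floor of 3 counts, such as Klrc2 in CD4 Tfh.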

Other observations

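The family, locus, marker, carry-over and overlap tests in this part and their bounds were chosen only after the results had been seen, as were all genes of this part that lie outside the rule for naming genes. Genes of the TNF receptor superfamily were lower in CD8 Tfc in 5 of 17 cases and higher in 1, Tnfrsf13c. Tnfrsf4, which encodes OX40, was 154 and 124 CPM in CD4 Tfh and 33.0 and 28.0 CPM in CD8 Tfc (log2 −2.18 ± 0.18 SE, adjusted p = 3.9e-04, edgeR), the reverse of its ligand gene Tnfsf4. Tnfrsf18 and Tnfrsf8 were at −1.14 and −1.96. Tnfrsf13b had 63.5 and 61.3 CPM in CD4 Tfh and 32.3 and 30.1 CPM in CD8 Tfc, and Tnfrsf19 had 12.4 and 11.6 against 4.00 and 1.99 CPM. Semaphorins were higher in 4 of 12 cases and lower in 0, led by Sema4a with 200 and 217 CPM in CD8 Tfc and 33.5 and 57.6 CPM in CD4 Tfh (log2 2.19 ± 0.25). The chemokines Ccl3, Ccl4 and Ccl5, 3 of 9 of their family, were higher by 1.62, 1.21 and 1.11, and 0 were lower. Over 368 gene families grouped by symbol stem and tested in both directions with Fisher's exact test (1-sided), none passed adjustment, with 20 tests at an unadjusted p under 0.05. The adjusted p was 0.220 for the lower TNF receptors and for the higher semaphorins and 0.478 for the higher chemokines. The smallest, 0.205, was that of the apolipoprotein L family, which went both ways, with 4 of 9 cases higher and 3 lower.

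A run of natural killer receptor genes on chromosome 6 was higher throughout, from Klrd1 (129588092 to 129598775) over Klrk1, Klrc3 and Klrc2 to Klrc1 (129666015 to 129682852), with no other protein-coding gene of the table between them. Maf and Cebpa, transcription factors of the follicular helper list, were at −3.10 and −3.63, and Ascl2, which promotes follicular homing, had 9.02 and 11.7 CPM in CD4 Tfh against 1.33 and 1.25 CPM in CD8 Tfc. Tnfsf11, the RANK ligand gene, was at −2.90. Ctsw, Crtam and Nkg7, genes of cytotoxic lymphocytes, were at 3.55, 3.08 and 2.10.

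B cell, neutrophil and erythroid markers were high in CD8 Tfc 1, where 39 of the 44 tested members were over 2 times their level in CD8 Tfc 2, and CD4 Tfh 1 exceeded CD4 Tfh 2 over 2 times for 10 of 19 B cell, 9 of 10 neutrophil and 11 of 15 erythroid members. RNA or cells of these lineages in CD8 Tfc 1 alone may be a source, although the CD8, CXCR5 and PD-1 gate should exclude such cells. A source in that library alone would not account for the higher levels in CD4 Tfh 1 than in CD4 Tfh 2. CD8 Tfc 2 also lay above CD4 Tfh 2 for 31 of the 44 members. By list these were 12 of 19 B cell, 10 of 10 neutrophil and 9 of 15 erythroid members. The whole neutrophil list summed to 15.1 CPM in CD8 Tfc 2 and 2.78 CPM in CD4 Tfh 2, so its members were low in both. Members of a list moved together, with estimated correlations of 0.607, 0.985 and 0.929, so they are not separate observations. Expression of these genes by CD8 Tfc cells in both libraries may be another source. Of the 44 members, 30 lay above the same-numbered CD4 Tfh library in both, namely 12 B cell, 10 neutrophil and 8 erythroid ones. However, CD8 Tfc 2 lay above both CD4 Tfh libraries for only 9, few enough to exclude this source by the bound first set. That bound was changed after the values had been seen. Abundant members were Cd74 (95.3 against 7.84 CPM in CD8 Tfc 1 and 2), Hbb-b1 (64.1 against 15.6) and S100a9 (59.0 against 4.70), while Tfrc, at 181 and 150.4 CPM, and Cd22, at 84.8 and 85.3 CPM, did not follow. These sources cannot be told apart, because each combination of group and replicate number has 1 library.

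Cd4 in CD8 Tfc 1 exceeded CD8 Tfc 2 by 2.70% of its mean CD4 Tfh level. Carried-over CD4 Tfh cells as the whole cause were argued against, since they would add this share of every CD4 Tfh transcript, but over 24 other called genes at least 8-fold lower, with a CD4 Tfh mean of at least 20 CPM, the share had a median of 0.779% (quartiles −0.401% and 2.10%), with 4 of them above Cd4. The upper quartile was the bound first set, and under the highest gene, which replaced it for a time after the value had been seen, this source would stay open. Regulatory T cells are another possible source. In CD8 Tfc 1, 5 of the 12 called members of their list were over 2 times higher than in CD8 Tfc 2. These included Foxp3, Gpr83 and Ebi3, while Itgb8, Nt5e and Izumo1r were not higher. The latter were at 1.33, 53.8 and 79.5 CPM in CD8 Tfc 1 and at 1.36, 58.4 and 89.9 CPM in CD8 Tfc 2. Their levels in CD4 Tfh 2 were 20.1, 181 and 402 CPM. Adding the 2.70% of Cd4 would not double them. Foxp3, however, rose by a larger share, with 3.45 and 0.627 CPM in CD8 Tfc 1 and 2 and 19.0 and 19.3 CPM in CD4 Tfh. How much of each member's CD4 Tfh level came from regulatory T cells is not known, so no share can be set for this source. The CD8 gate should remove both kinds of cell. Regulatory T cells stay open, with some members of their list raised in CD8 Tfc 1 and others not.

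Several genes of lymphocytes were listed at 0 in all 4 libraries, among them B2m (chromosome 2, 122147687 to 122153082), the light chain of MHC class I molecules. B2m lies inside the span of Patl2. For genes inside another gene's span, absence of the transcripts was argued against. Protein-coding genes of this kind were listed at 0 more often than those with no overlap, by 72.4 percentage points. Of 18 list members at 0, 10 lay inside another gene. For the other members, such as Il9, Ccl19 and Ifi47, and for all 3719 genes at 0 with no overlap, absence was not argued against. Reads in overlapping spans may have been left uncounted, since 93.7% of 527 genes inside another gene were at 0, against 21.6% of 17221 with no overlap. Partly overlapping genes were at 0 in 4.60% of 2825 cases. No biological explanation by group was tested, since the genes were chosen as being at 0 in both groups.

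On chromosome 14, between 3049285 and 7658936, 33 of 35 tested gene entries were lower in CD8 Tfc, with a median log2 fold change of −2.36. The ends of this block were set by entries of predicted genes (Gm symbols) already called lower, so the share of lower entries in it is not a test. Of the 33, 31 had such symbols. Of the deposited values of the 33, 99.2% were not whole, against 44.4% for all tested entries. Whether these entries share reads was not tested.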
